A study of Homo sapiens with 2 samples.

How the data were processed

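The data are the peak lists of CLIP-seq libraries for MSI2 from NB4 cells, 1 list for each of 2 replicates of 1 group. Per the labels' protocols, cells were crosslinked with ultraviolet light on ice and the libraries were built with an anti-MSI2 antibody. Per the submitters' processing notes, cutadapt, Bowtie 1.0.0 and STAR 2.3.0e were used and the genome build was hg19. The names of the deposited lists record that poly(A) and adapter sequence had been trimmed and duplicate reads removed, and each library had its own list. The peak caller and its settings are not given in the sources used here. The lists have no header. Each line holds a chromosome, a start, an end, a name, a p-value, a strand and a short inner interval within the peak. The p-value of each peak is the authors' own, as deposited, and was under 0.05 in every peak of both lists. Whether it was corrected for the number of peaks is not given in the sources used here, and it was used only to describe, rank and filter peaks within a list. The name holds an Ensembl gene ID with its version, a running number, and a last number that no header or label explains. This last number, the tally, was 3 or more in every peak and rose as the p-value fell (Spearman rho across peaks -0.94 in replicate 1 and -0.92 in replicate 2), and it was taken to behave like a number of reads.

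The total number of reads in each library is not given in the files, so the sum of the tallies, 155598 and 133644, stands for what was called as peaks and not for sequencing depth. If tallies are reads, a median of 4 leaves most peaks resting on very few fragments. Duplicates had been removed without a stated molecular identifier, so binomial intervals cover counting error only. The labels number the replicates but do not say that they came from separate cultures, so differences between these samples may be technical. The p-values come from placements within genes and from flips or swaps over genes, and none measures the spread between cultures. The same interval was listed under more than 1 gene ID for 595 intervals in replicate 1 and 684 in replicate 2, giving 729 and 840 repeated peaks. These were kept as deposited, with an alternative that counted each interval once. Peaks of one gene sometimes touched end to end, 835 times in replicate 1 and 1781 times in replicate 2, and an alternative merged peaks within 50 nt.

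A peak was called shared if a peak of the other replicate overlapped it by 1 nt or more on the same strand, and the shared peaks of replicate 1 are the reproducible peaks. The share was tested one-sided against 1000 random placements of each peak of the other replicate within its gene. Gene bounds of hg19 were not used here, so a gene's bounds were the first and last peak under its ID in either replicate, the fallback fixed before the data were examined. Genes with a single peak or with close peaks leave little room for placement, so placement within 5 kb, within 500 nt, and over genes spanning 10 kb or more were also run. Relative position was measured from the midpoint of a peak, leaving out the peaks that set the span, in genes spanning 10 kb or more, with a one-sided sign-flip permutation test of gene medians against the middle of the span and 100000 flips. Shares carry 95% Wilson intervals, and 1000 bootstrap samples over genes gave the other intervals. Quartiles were taken of the deposited p within each list. The shares by tally and by width, the comparison of chromosomes by gene-wise swaps (10000), the difference in position between shared and other peaks, the runs of peaks at gene ends and the mitochondrial peaks were chosen after seeing the data. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

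The placement test and the position test were tested on simulated data. The simulation covered only the 16575 peaks of replicate 1 in genes spanning 10 kb or more, not the genes with little room for placement. With 0, 10 and 30% of these peaks given a partner at the same place, the placement test recovered 0.069, 9.93 and 29.7 percentage points over chance. The simulated background was placed uniformly within each span, as in the test itself, so the result at 0% was fixed in advance. The simulation does not show how the test behaves when both libraries cluster in the same parts of genes. Uniform positions along the same genes gave a sign-flip permutation p of 0.92. This too was fixed in advance, as the positions were drawn evenly within spans taken from the real peaks. It does not cover the step in which peaks that set the span are left out. Alternatives covered the overlap that counts as shared (reciprocal 50%, midpoints within 50 nt, extension by 100 nt), stricter lists (the stronger 50% and the strongest 10% by p), merged peaks, lists of equal size, each replicate alone and a minimum span of 50 kb.

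The rule for named items, fixed in advance as well, had 4 parts. They were the members of the aryl hydrocarbon receptor list with MSI1 and MSI2, up to 4 members of each other list, the 15 genes with the most reproducible peaks, and the 10 genes whose best reproducible peak had the strongest p in the weaker replicate. Only the last 2 parts could be applied. The table of gene names used here, of assembly GRCh38.p14, has an empty column for Ensembl IDs, so 0 of the 8801 gene IDs could be matched, and the files do not pair IDs with names. For this reason the planned shares of 19 gene lists holding 466 genes are not reported here. The makeup of the peaks by untranslated region, coding exon and intron, and the density of the UAG motif, were planned too and are not analysed here, as no sequence or annotation of hg19 was used. Fisher's exact test of genes found in both replicates was not run, because it needed the full set of annotated genes as its universe.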

Results

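Musashi-2 (MSI2) is an RNA-binding protein of the Musashi family. Its binding sites were mapped by CLIP-seq in NB4, an established human acute promyelocytic leukaemia line. In this assay ultraviolet light crosslinks proteins to the RNA they touch, an antibody recovers one protein, and the RNA fragments bound to it are sequenced. Both libraries belonged to 1 group, and each was labelled with the same number of cells and a crosslinking dose of 400 mJ per square centimetre. No control antibody, input RNA or MSI2-depleted library was analysed here, so the comparison that the design gives is between replicates. It addresses how repeatably each peak was found and under which gene IDs, in a study concerned with MSI2 and aryl hydrocarbon receptor signalling in blood stem cells. It cannot separate MSI2 binding from repeatable background. Replicate 1 held 25920 peaks under 7252 gene IDs, with a median width of 42 nt (interquartile range 29 to 54), and replicate 2 held 25243 peaks under 7101 gene IDs, with a median width of 39 nt (interquartile range 26 to 51). Each peak's name ends in a whole number, called its tally here, that was 3 or more in every peak. The tally behaved like a number of reads, though no header or label says so. Tallies summed to 155598 in replicate 1 and 133644 in replicate 2, with a median of 4 in each and a maximum of 92 and 106. Peaks with the lowest tally, 3, made up 35.7% of replicate 1 and 45.3% of replicate 2.

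MSI2 peaks recurred at the same positions in both libraries far more often than random placement within genes gave. In replicate 1, 9246 peaks, or 35.7% (95% Wilson interval 35.1% to 36.3%), were overlapped on the same strand by a peak of replicate 2. In replicate 2, 9405 peaks, or 37.3% (36.7% to 37.9%), were overlapped by a peak of replicate 1. Resampling whole genes gave 95% intervals of 34.9% to 36.4% and 36.5% to 38.1%. Random placement of the other replicate's peaks between the first and last peak of their own gene gave 7.01% for replicate 1, with a highest value of 7.35%, and 7.24% for replicate 2, with a highest value of 7.69%. The observed shares were 5.09 and 5.15 times those means, and the one-sided permutation p was 0.001 in both cases, the smallest that 1000 placements can give. Most of the overlapping peaks had short inner intervals, as deposited, at nearly the same place. The centres of these inner intervals lay a median of 7 nt apart, and 66.9% of them lay within 10 nt of each other. The median overlap of the peaks was 38 nt. On the opposite strand, 2 peaks of each replicate were overlapped by a peak of the other, though peaks are listed under genes, so this can occur only where genes lie on both strands. The level of chance depended on the space allowed for placement. It was 3.12% and 3.25% within 5 kb of each peak's own position, 9.75% and 10.1% within 500 nt, and 2.46% and 2.58% over the genes whose peaks span 10 kb or more, where the observed shares were 33.9% and 35.6%. The spans include introns and no control library was analysed, so recurrence above chance does not by itself show MSI2 binding.

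At the level of genes, 5552 gene IDs carried peaks in both libraries, which was 76.6% of those in replicate 1, 78.2% of those in replicate 2 and 63.1% of the 8801 seen in either. A reproducible peak, meaning a replicate 1 peak overlapped by a replicate 2 peak, was present in 4001 gene IDs. Of the genes with peaks in both libraries, 3990 (71.9%) had at least 1 reproducible peak, and the other 1562 had peaks in both libraries but none at a shared position. Reproducible peaks were spread over many gene IDs: 1932 genes had exactly 1 reproducible peak, 442 had 5 or more, and 57 had 10 or more. With no control library, these counts do not separate MSI2 binding from repeatable background. The 100 genes with the most reproducible peaks held 1043 of them, or 11.3%. The number of peaks per gene correlated between the libraries across the genes found in both, with a Spearman rho of 0.65 and a Pearson r of 0.68 on log2(1 + peaks). These are correlations across genes, which are not independent replicates. Genes seen in 1 library alone were mostly genes with a single peak, at 64.8% of the 1700 found only in replicate 1 and 61.6% of the 1549 found only in replicate 2. Among the genes found in both, 24.2% had a single peak in replicate 1 and 26.6% in replicate 2. A stricter list lowered the counts, to 3572 genes and 5771 reproducible peaks with the stronger 50% of each list by p, and to 1063 genes and 1428 reproducible peaks with the strongest 10%. The share of peaks shared rose to 55.1% and 57.1% with both lists cut to their strongest 10%. A match then counted only if the other peak was also in the strongest 10% of its list.

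The genes with the most reproducible peaks are given by their peaks' hg19 positions, because the files do not pair gene IDs with names. The gene with the most, ENSG00000169710.6, had 18 between positions 80036280 and 80054323 of chromosome 17 on the minus strand, among 31 peaks in replicate 1, and replicate 2 listed 42 peaks there. ENSG00000167978.12 had 17 between 2806482 and 2821258 of chromosome 16 on the plus strand, among 24 peaks in replicate 1, with 27 listed in replicate 2. A gene on the minus strand of chromosome 8, with peaks from 48685820 to 48872603, also had 17, and a gene on the minus strand of chromosome 7, with peaks from 5346658 to 5430258, had 16. Genes at 54624954 to 54651385 of chromosome 12, 96315323 to 96373020 of chromosome 5 and 245014592 to 245027379 of chromosome 1 had 15 each. These genes differed in where their sites lay. The minus-strand gene at 24964407 to 25047212 of chromosome 12 had 12 reproducible peaks inside its 82.8 kb span, and 100% of them lay in the 3'-most 10% of it. At the chromosome 5 gene 60% lay there, at the chromosome 16 gene 5.88% did, and at the chromosome 1 gene 0 of 15 did. Whether these sites lie in exons, introns or untranslated regions is not reported here, because no exon positions of this genome build were used.

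The strongest single sites were chosen among the shared peaks, so their presence in both libraries was fixed by the choice. Most had close coordinates in the libraries. An exception was a minus-strand peak at 65622298 to 65622473 of chromosome 11, with a tally of 77, which ended at 65622398 in replicate 2, with a tally of 47. With no control library, none of these sites can be told from repeatable background. By the p that the authors' lists give in the weaker replicate, the strongest was a minus-strand peak at 91852787 to 91852929 of chromosome 1 in replicate 1 and 91852792 to 91852932 in replicate 2. It was listed under ENSG00000162669.11, with a tally of 90 and a p of 2.66e-90 in replicate 1, and a tally of 106 and a p of 3.10e-106 in replicate 2. The next was a plus-strand peak at 20704379 to 20704482 of chromosome 12, listed under ENSG00000172572.6. Its tallies were 77 and 73 and its p-values 3.74e-91 and 6.66e-88. All peaks listed under these gene IDs lay within 0.349 kb for the first and 0.119 kb for the next, so neither ID had peaks elsewhere. No sequence was used here, so whether reads of repeated sequence were placed at these positions was not tested. On chromosome 11, a plus-strand peak at 18429005 to 18429132 had tallies of 83 and 80. Tallies of 75 and 73 belonged to a minus-strand peak at 26227335 to 26227453 of chromosome 1, and tallies of 76 and 62 to a minus-strand peak at 77338372 to 77338510 of chromosome 15. A plus-strand peak at 135539757 to 135539862 of chromosome 6 had tallies of 60 and 52, and a minus-strand peak at 47387674 to 47387827 of chromosome 2 had tallies of 60 and 49. Across all 9246 pairs of shared peaks, the tallies correlated with a Spearman rho of 0.60 and a Pearson r of 0.68 on the log2 scale, over peaks and not over independent samples.

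Along genes, MSI2 peaks were concentrated toward the 3' end. Relative position was 0 at the first peak at the 5' end and 1 at the last at the 3' end. It was summarised by the median for each gene and then the median of these over genes, here and in the medians of position below. Over 1823 genes whose peaks span 10 kb or more, this value for the shared peaks of replicate 1 was 0.92 (95% bootstrap interval over genes 0.91 to 0.93). The gene's own median lay beyond the middle in 1479 genes, or 81.1%. Of these 4979 peaks, 51.8% lay in the 3'-most 10% of the span and 7.71% in the 5'-most 10%. Their median distance to the 3' end of the span was 2.80 kb, against 24.6 kb to the 5' end. Replicate 2 gave a median of 0.93 over 1862 genes, with 52.6% of the shared peaks in the 3'-most 10%. In genes whose peaks span 50 kb or more, the replicate 1 median was 0.96 and the share in the 3'-most 10% was 59.3%. Peaks found in 1 replicate alone leaned the same way but less, with medians of 0.76 in replicate 1 and 0.74 in replicate 2 and with 37.1% and 34.2% of peaks in the 3'-most 10%. In replicate 1 the gap of 14.8 percentage points between shared and other peaks in that part was 5.06 points (95% bootstrap interval 2.85 to 7.25) within equal tallies. Within the genes that held both kinds, shared peaks lay further toward the 3' end by a mean of 0.064 ± 0.008 (SE over 1564 genes) in replicate 1, higher in 969 genes and lower in 595. In replicate 2 this difference was 0.104 ± 0.009 (SE over 1527 genes), higher in 1017 genes and lower in 510. The gene medians, tested against the middle of the span, and the within-gene differences each had a one-sided sign-flip permutation p of 1e-05 over genes, the smallest that 100000 flips can give. The spans are those of the peaks and not of annotated genes, and they include introns, so they do not separate 3' untranslated regions from the spacing of exons. With no control library, the lean toward the 3' end and its p-value cannot tell MSI2 binding from repeatable background. The span's ends were set over both replicates together. Of a shared pair at an end, a partner lying just inside was kept. An unshared peak that set an end was always left out. This can add shared peaks alone near the ends, so the gaps between shared and other peaks may partly come from it. With peaks within 500 nt of the ends left out, the replicate 1 shared median was 0.85, and the other peaks were not tested in this way.

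**Figure D1:**
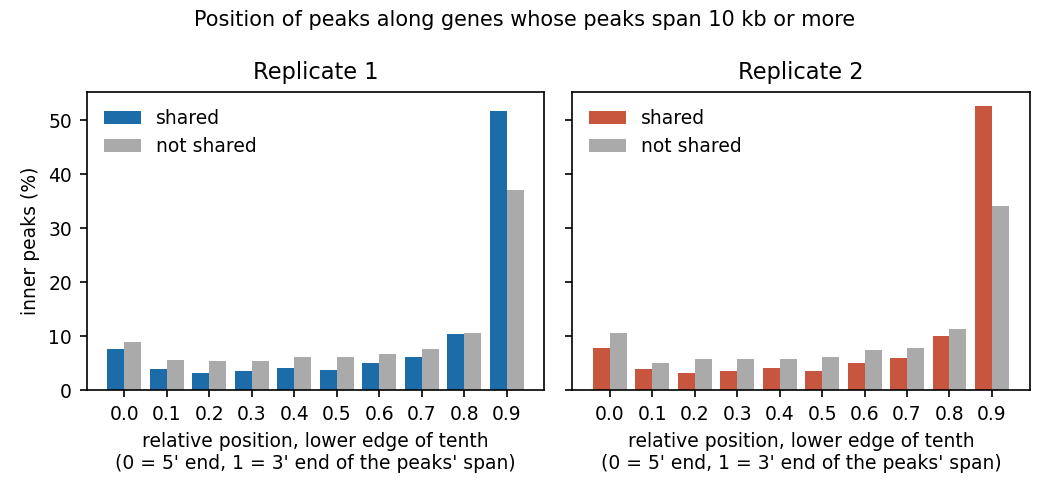
Percentage of peaks (vertical axis) in each 10% of the span from the first to the last peak of a gene (horizontal axis, 0 at the 5' end and 1 at the 3' end), for genes whose peaks span 10 kb or more, without the peaks that set the span (their shared partners just inside it were kept). Coloured bars are peaks shared with the other replicate and grey bars are peaks not shared: the last bar reaches 51.8% and 52.6% for shared peaks and 37.1% and 34.2% for the others.

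Strong peaks were nearly always found again and weak ones seldom were. With a tally of 3, 11.9% of the peaks of replicate 1 (95% Wilson interval 11.3% to 12.6%) and 15.5% of those of replicate 2 (14.9% to 16.2%) were shared. Chance was not computed by tally. Over all peaks it was 7.01% and 7.24% within genes, and 9.75% and 10.1% within 500 nt, so much of the sharing at a tally of 3 may be chance overlap. With a tally of 5 the shares were 35.1% and 45.7%, with 8 to 9 they were 65.7% and 74.5%, and with 10 to 14 they were 81.9% and 85.1%. With a tally of 20 or more they reached 97.3% (95.7% to 98.2%) and 96.2% (94.2% to 97.6%). Ordered by p from strongest to weakest, the quartiles of replicate 1 had shares of 73.2%, 35.1%, 19.5% and 14.8%. In replicate 2 the shares were 72.7%, 40.6%, 13.7% and 22.03%, so that the weakest quartile was shared more often (21.02% to 23.07%) than the one before it (12.9% to 14.6%). Shared peaks were also wider than the others, with a median of 52 against 37 nt in replicate 1 and 47 against 35 nt in replicate 2. A wider peak is more easily overlapped by definition, and this difference was not adjusted for chance or for tally. The Wilson intervals cover counting error only, since peaks in one gene are not independent. Extending each peak by 100 nt raised the share of the weakest quartile of replicate 1 to 29.1%, but it also raised chance over all peaks of that replicate to 20.2%, against an observed 48.5%.

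**Figure D2:**
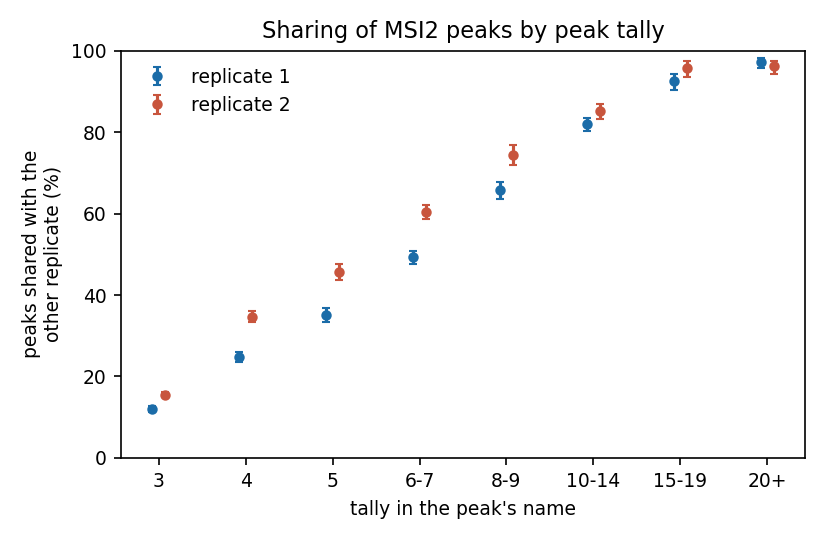
Percentage of peaks overlapped by a peak of the other replicate (vertical axis) by the tally in the peak's name (horizontal axis), with 95% Wilson intervals as bars, replicate 1 in blue and replicate 2 in red. The share climbs from 11.9% and 15.5% at a tally of 3 to 97.3% and 96.2% at 20 or more.

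The libraries divided their peaks differently among the chromosomes. Chromosome 19 held 1028 peaks (3.97%) in replicate 1 and 1488 (5.90%) in replicate 2, a log2 ratio of shares of 0.57 (95% bootstrap interval over genes 0.45 to 0.69). Chromosome 22 held 469 peaks in replicate 1 and 610 in replicate 2, a log2 ratio of 0.42 (0.22 to 0.63), and chromosome 16 held 1068 and 1193, a log2 ratio of 0.20 (0.08 to 0.33). Chromosome 4 held 937 peaks in replicate 1 and 751 in replicate 2, a log2 ratio of -0.28 (-0.43 to -0.14), and chromosomes 2, 8, 10 and 13 also held lower shares in replicate 2. Of the 24 chromosomes compared, counting the mitochondrial one, 3 had a higher and 5 a lower share in replicate 2 at a Benjamini-Hochberg adjusted p under 0.05. The test was a two-sided permutation that swapped the replicates gene by gene. For chromosome 19 the raw permutation p was 0.0001, the smallest that 10000 swaps can give, and the adjusted p was 0.00080. Merging peaks within 50 nt left 5 chromosomes past the threshold, namely 16, 19 and 22 with a higher share in replicate 2 and 2 and 4 with a lower one. Counting each gene once, in place of each peak, gave 6, of which 16, 17, 19 and 22 had a higher share in replicate 2 and 3 and 14 a lower one, so that none of the 5 lower calls above passed. The log2 ratio was then 0.26 for chromosome 19, 0.24 for chromosome 22 and -0.14 for chromosome 4. With 1 library per replicate, this compares these libraries and has no further replicate.

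**Figure D3:**
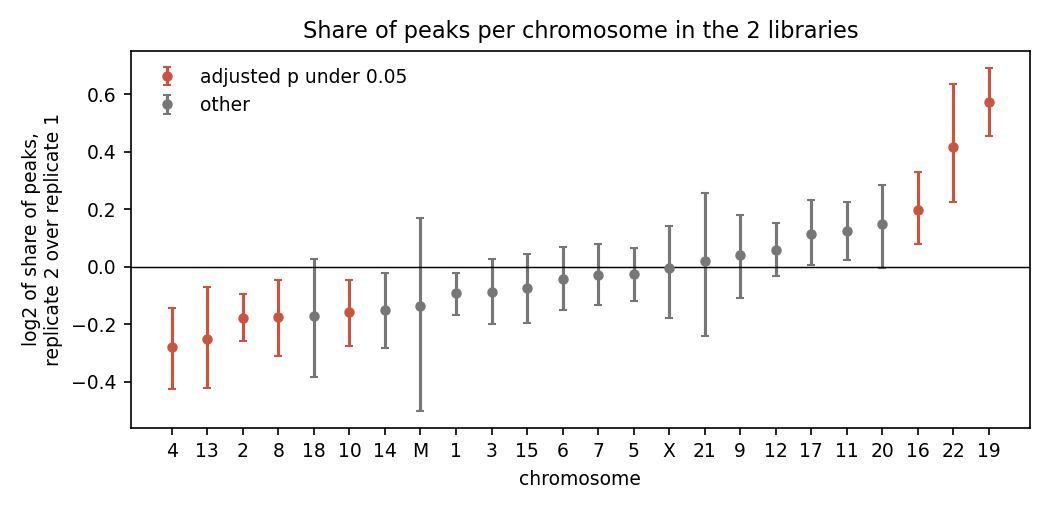
Log2 of the share of peaks on each chromosome in replicate 2 over that in replicate 1 (vertical axis), by chromosome in rising order (horizontal axis), with 95% bootstrap intervals over genes as bars and red for adjusted permutation p under 0.05. Chromosome 19 lies highest at 0.57 and chromosome 4 lowest at -0.28.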

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

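Placement within 500 nt, genes spanning 10 kb or more, intervals counted once, peaks near the span's ends left out, and all alternatives for chromosomes were chosen after seeing the data. Of 58 recomputed values, 47 kept their direction and their side of the threshold, or stayed within the margin set for a value without a test. Counts of chromosomes were judged by their number and not by which ones passed. The share of shared peaks ran from 26.8% to 55.1% in replicate 1 and from 27.5% to 57.1% in replicate 2, above chance in each of 11 alternatives (one-sided permutation p 0.0099, the smallest that 100 placements can give). The median of the gene medians of position ran from 0.82 to 0.96 over 8 alternatives, and the correlation of peaks per gene from 0.64 to 0.65 over 4. Counts fell with shorter lists by construction: the stronger 50% by p left 3572 genes in both replicates and 5771 reproducible peaks, and the strongest 10% left 1063 and 1428. Leaving out 1 replicate makes every peak of the other count, 25243 to 25920. A reciprocal overlap of 50% lowered the share in the strongest p quartile of replicate 1 to 58.7% and in the weakest to 10.0%, and extension by 100 nt, which widens what counts as overlap, raised them to 82.6% and 29.1%. Chromosomes past the threshold numbered 8 as deposited and with each interval counted once, 5 with peaks merged within 50 nt, 10 with the stronger 50%, and 6 with each gene counted once (the cause was not tested). Chromosomes 19 and 22 passed in every one of these settings, and chromosome 16 in each but the stronger 50%. With each gene counted once, chromosomes 2, 4, 8, 10 and 13 no longer passed, and chromosomes 3 and 14 (lower in replicate 2) and 17 (higher) did. Alternatives for gene lists, region classes and the UAG motif were not run. At a tally of 3, a peak missed in the other library cannot be told from one under the calling limit.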

Other observations

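The tests of runs at gene ends, of mitochondrial peaks and of each explanation were chosen after the patterns they address had been seen, while the shares by p quartile and the positions along genes were planned. Runs of close MSI2 peaks were longer on average at the 3' end of a gene's span of peaks than at the 5' end, though most genes had a lone last peak. The ends are those of the first and last peak and not of annotated genes. Only genes with more than 2 peaks in the replicate, spanning 10 kb or more, were used. Peaks that touch were counted separately, and a version with merged peaks was not run. Exon layout and repeatable background were not tested as causes. Counting from the last peak inward while gaps stayed at 500 nt or less, the run at the 3' end held 1.77 peaks on average (SD 1.14) over 1947 genes of replicate 1, against 1.19 (SD 0.48) at the 5' end. The 3' run was the longer in 786 of these genes and the 5' run in 195, and they were equal in 966. A 3' run of 2 or more peaks was present in 43.7% of the genes. Replicate 2 gave 1.84 (SD 1.28) against 1.27 (SD 0.58) over 1857 genes, with the 3' run longer in 741, the 5' run in 272 and both equal in 844. In replicate 2 a 3' run of 2 or more was present in 45.3% and a 5' run of 2 or more in 22.5%. The one-sided sign-flip permutation p was 1e-05 in each replicate, the smallest that 100000 flips can give. The longest 3' runs held 10 and 11 peaks.

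The mitochondrial genome carried 70 peaks in replicate 1 and 62 in replicate 2, of which 65 and 59 lay on the plus strand. They were 0.27% and 0.25% of the peaks but 1.15% and 0.93% of the summed tally, with median tallies of 18.5 and 13 against 4 for nuclear peaks. Of these, 71.4% (95% Wilson interval 59.9% to 80.7%) and 80.6% (69.1% to 88.6%) were shared between replicates. Nuclear peaks weighted to the same tallies were shared at 89.0% and 85.0%, above the interval of the mitochondrial share in replicate 1 and inside it in replicate 2.

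Chromosome 19 held a larger share of the peaks in replicate 2, with a log2 ratio of 0.57. Weak peaks alone do not account for it, since the stronger 50% of each list gave 0.66 (95% bootstrap interval 0.53 to 0.82), and neither do a few genes with many peaks, since counting each gene once left 0.26 (0.14 to 0.38), though that is a smaller ratio. An unequal makeup of the libraries was examined as well. Across 23 chromosomes, the log2 ratio of tallies at shared peaks rose with that of the peaks not shared (Spearman rho 0.61, permutation p 0.0026, and Pearson r 0.76, permutation p 0.00020). Any cause that put more reads on a chromosome in either library would raise both, so this result does not single out a cause. Without chromosomes 19 and 22, rho was 0.49 (permutation p 0.023) and r was 0.47. What made the libraries differ stays open, GC content and RNA levels among the candidates, and no biological explanation was tested because the design has 1 group.

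In replicate 2, peaks in the weakest p quartile were shared more often than those in the quartile before it, by 8.30 percentage points. Their genes held more replicate 1 peaks (a mean of 5.48 against 4.71) and they were wider (a median of 36 against 24 nt), at a median tally of 3 in each. Standardised for the number of replicate 1 peaks in the gene, the difference was 6.15 points (95% bootstrap interval 4.76 to 7.44), and standardised for width it was 7.06 points (5.63 to 8.50), so neither accounts for all of it. The caller may set p by the read density of the gene, so that an equal tally gets a weaker p in a highly covered gene; this stays open, as does standardising for both at once, and no biological explanation was tested.

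Shared peaks of replicate 1 lay in the 3'-most 10% of the span more often than peaks not shared, by 14.8 percentage points. Within equal tallies the difference was 5.06 points (95% bootstrap interval 2.85 to 7.25), so peak strength may carry much of it. Tallies are small counts, and equal tallies need not mean equal strength, so strength may also carry some or all of the rest. What is left may partly come from the partners of peaks that set the span, which were kept only among shared peaks. Denser peaks near the 3' end raise chance overlap there, to 14.7% against 6.57% in the rest of the span under placement within 500 nt. The observed shares were 46.4% and 32.1%. The excess over chance was higher in the 3'-most 10% as a difference, by 6.11 points (4.55 to 7.63), but lower as a multiple of chance. It was not adjusted for tally either, so these values do not settle whether denser peaks account for the pattern. Exon layout and RNA levels stay open, and no biological explanation was tested because there is 1 group and no control library.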
